A study of Mus musculus with 6 samples.

How the data were processed

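RNA from 3 haploid and 3 diploid mouse ES cell samples was hybridised as biotin-labelled target to Affymetrix arrays, 1 array per sample, per the labels' protocols. The titles name a line for each haploid sample but only a replicate number for each diploid sample. Each sample is called a line here. The deposited table holds 1 log2 value per probe set and array, made with RMA per the submitters' processing notes. RMA, in general use, corrects background, normalizes quantiles between arrays and summarises the probes of a set. Its software, version and settings, and whether the 6 arrays were processed together, were not given in the sources used here. The values ran from 2.62 to 15.2 and the quartiles of the arrays were close to each other, which is the form that RMA gives. Normalization of this kind sets all arrays to one distribution, so a change in the total RNA of a cell cannot be seen, and every fold change is relative to the bulk of genes. RMA also compresses large differences of dim genes.

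The table had 45101 probe sets. The 64 control probe sets were left out of the tests and served only for the 3' minus 5' check. Gene symbols came from the platform annotation in GEO, which gave 34945 probe sets 1 symbol, 932 several and 9160 none; probe sets with several or no symbol were not named. Through their Entrez numbers 34741 probe sets matched the RefSeq gene table of assembly GRCm38.p6, which gave the chromosome and the order of genes; 0 symbols needed an update. No coordinate is printed, because the build behind the arrays was not given. A gene was represented by the probe set with the highest mean over all 6 arrays, which gave 18193 genes (17404 autosomal, 617 on X, 9 on Y and 162 with no chromosome). Of these, 9010 had more than 1 probe set. Among 4393 genes with at least 2 probe sets above the median level, 16 had probe sets that passed in opposite directions and 213 had probe sets that differed by over 1 (log2). Among the genes named in the text, such probe sets had opposite signs for Atrx (from -0.39 to 1.46), Nr5a2 (from -1.37 to 0.27), Meg3 (from -0.78 to 0.67), Ccnd3 (from -0.09 to 1.05) and Esrrb (from -0.19 to 0.29). They had 1 sign but differed by about 1 or more for Enpp3 (from -4.19 to -2.60), Dnmt3a (from -1.51 to -0.37), Pdk1 (from -2.26 to -1.22) and Sox4 (from -1.79 to -0.79).

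Each line counted as 1 replicate, and its group came from the labels. The design named biological triplicates. Replicate numbers only name a line. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings, two-sided), with no covariate, no filter on dim genes and a Benjamini-Hochberg adjusted p of 0.05 over all genes. Every adjusted p of a gene is from limma. Folds of genes whose dimmer group had a mean under the lowest of the arrays' lower quartiles (4.80) are given as lower bounds, a limit chosen after the data were examined. SE is the moderated standard error of the log2 difference. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 30 lists, and again with an estimated correlation. X-linked and autosomal genes, and each of 19 autosomes, were compared over genes whose mean lay above the median of all genes, on values centred per gene over the 6 arrays. The X-linked difference had an exact permutation test over 20 labelings, whose smallest p is 0.1. The line contrast used limma with 3 groups (diploid, haploid replicates 1 and 2, haploid replicate 3).

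The genes named in the text followed a rule. It took the 12 largest increases and 12 largest decreases that passed with groups not overlapping. From each list it took up to 4 members that passed, with the largest change, or the 2 with the highest mean where none passed. It further took a fixed set of pluripotency, sex chromosome, imprinted and p53 genes, and the 4 X-linked genes with the largest change in each direction. The rule gave 143 genes, of which the text names a part; genes named outside it are marked as chosen after their values were seen. Lists, tests, this rule and most alternatives were fixed before the data were examined. Some members of the fixed lists had no probe set with a single symbol and were not analysed here.

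The alternatives were another quantile normalization, aligned array medians, genes above the median level, the mean of a gene's probe sets, every probe set on its own, omission of probe sets whose names mark possible matches to several transcripts, eBayes with trend and robust settings, array weights, a 2-fold threshold, autosomal genes outside the imprinted lists, and omission of each array in turn, where probe sets kept their choice. After the data were examined, the omission of chromosomes 6, 8, 11, X and Y and the subtraction of each chromosome's median shift were added. The steps were tested on simulated data with 200 changed genes among 18193. For haploid against diploid, 86% of changes of 1 (log2) and 98% of changes of 2 were recovered, and 6.6% of the calls were unchanged genes. A chromosome lowered by 0.3 was the 1 autosome called, and no list was called where none was changed. The simulated genes varied independently of each other, so this does not test the list and autosome calls where genes vary together. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

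The RNA quality control of glyceraldehyde phosphate dehydrogenase, the 3' minus 5' difference, lay between -0.09 and -0.01 (log2) on all 6 arrays. That of beta-actin separated the groups, with 0.34 to 0.46 in the diploid and 0.18 to 0.24 in the haploid lines. No 2 arrays held identical values, and the highest correlation of a pair was 0.9964. Labels gave no scan date or batch, so batch effects could not be tested. The values are on the scale of the arrays, where signal over background limits dim genes.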

Results

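Gene expression was measured in embryonic stem (ES) cells, pluripotent cells derived from the early mouse embryo, on Affymetrix mouse GeneChip arrays. RNA was compared between 3 haploid lines, which carry 1 set of chromosomes, and 3 diploid lines, with 1 array per line. The sample titles name a line for each haploid array but only a replicate number for each diploid array. Each diploid array is called a line here, although the titles do not state that these lines were separate. The diploid lines were labelled male. All lines were grown in 2i medium, which holds inhibitors of the kinases MEK and GSK3, and were taken on day 2 after passaging. Haploid replicates 1 and 2 were of F1 CBAxB6 background at passages 24 and 21, and haploid replicate 3 was a transgenic line of mixed background at passage 11. The diploid lines were of 129 or 129Sv background, so strain and ploidy differed together. The p-values measure the spread between the arrays of a group, which the labels call biological replicates and which for the diploid arrays may not be separate lines. The share of cells that were still haploid at harvest was not given in the sources used here. The median log2 value of the probe sets lay between 6.31 and 6.33 on the 6 arrays, and the number of arrays limits the precision of every value.

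The comparison of haploid with diploid lines asked which genes differ with ploidy in the same medium. The Y-linked Eif2s3y, a subunit of a translation initiation factor, was lower by 6.39 ± 0.17 on the log2 scale (SE, n = 3 lines per group), or at least 84-fold, in the haploid lines (limma adjusted p = 4.66e-05). Its haploid values were 3.38 to 3.97. The diploid lines were labelled male, while a single set of chromosomes holds either X or Y. X-linked genes were expressed in the haploid lines, so a Y-linked difference follows the chromosomes present and is not read as regulation by ploidy. Where the mean of the dimmer lines lay under 4.80 (log2), the lowest of the arrays' lower quartiles, a fold is given as a lower bound. The ectonucleotidase Enpp3 was 18.3-fold lower, the lipid carrier Apod 11-fold lower, the prohormone-processing enzyme Cpe 10.7-fold lower, the actin-binding protein Cap1 8.24-fold lower and the glutathione transferase Mgst1 7.63-fold lower. The secreted protease Htra1 was 12.7-fold higher in the haploid lines (log2 difference 3.67 ± 0.14, limma adjusted p = 0.000281). Smtnl1 was 12.1-fold higher, the acyltransferase Gpat3 at least 10.4-fold higher, the laminin chain Lama3 8.57-fold higher and the scaffold protein Ush1c 8.06-fold higher. Of the largest increases, Gm364 was 21-fold, AI662270 14.9-fold and Zfp934 8.53-fold higher. AI662270 differed by 4.77 (log2) without the probe sets that may match several transcripts. Gm364, which is X-linked, stood at 9.31 in diploid replicate 1 and at 6.55 and 6.88 in the other diploid lines. It differed by 5.26 (log2) without diploid replicate 1 and by 3.62 with the X chromosome's shift subtracted. With the mean of a gene's probe sets the log2 difference was -3.34 for Eif2s3y, -2.01 for Enpp3, -1.70 for Apod, -1.94 for Cpe, -1.58 for Mgst1, 1.52 for Lama3 and 2.04 for Zfp934, and all 7 still passed.

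Across 18193 genes, 2707 passed an adjusted p of 0.05 in limma, 1441 of them higher and 1266 lower in the haploid lines. Of these, 414 were higher and 240 lower by at least 2-fold. The 3 haploid and the 3 diploid values did not overlap for 37.9% of all genes, against 10% by chance. The count was 970 without diploid replicate 3, 1196 without diploid replicate 2 and 1429 without haploid replicate 2. Of the genes chosen for naming, 65 no longer passed without diploid replicate 3, which moved the most calls. The number was 57 without diploid replicate 2 and 46 without haploid replicate 2. Diploid replicates 2 and 3 were the closest pair of arrays (Pearson's r across genes 0.9964). Diploid replicate 1 correlated with them at 0.9906 and 0.9913. Leaving out diploid replicate 2 or 3 breaks up that pair, so the lost calls do not mark either as the deviant array. The balance of directions depended on scaling: after quantile normalization 1255 genes were higher and 1419 lower, with array medians aligned 1303 and 1422, and with each chromosome's shift subtracted, a choice made after the data were examined, 1150 and 1552. The 3' minus 5' difference of the beta-actin control probe sets was 0.46, 0.38 and 0.34 (log2) in the diploid lines and 0.18, 0.24 and 0.24 in the haploid lines.

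Among the other named genes with large changes, the serine protease Prss23 was at least 6.43-fold lower and the matrix protein thrombospondin, Thbs1, 6.12-fold lower in the haploid lines. Without the probe sets that may match several transcripts, Prss23 differed by -0.28 (log2, limma adjusted p = 0.306), and with the mean of its probe sets by -1.64. Gm6958 (10.4-fold), Pdzrn4 (9.07-fold) and 1700019A02Rik (8.54-fold) were higher in the haploid lines, but with SDs of 1.86, 1.31 and 1.48 among them. Gm6958 did not pass without any one of the diploid replicates or without haploid replicate 2 or 3 (limma adjusted p = 0.0671 to 0.115), Pdzrn4 not without diploid replicate 2 or 3 or haploid replicate 2 (0.0517 to 0.0721), and 1700019A02Rik not without diploid replicate 2 or 3 or haploid replicate 2 or 3 (0.0586 to 0.0966). Without haploid replicate 1 they differed by 4.42, 3.93 and 3.92 (log2). Gm6958 differed by 2.65 without haploid replicate 3 and 1700019A02Rik by 2.49 without haploid replicate 2. With the mean of its probe sets Gm6958 differed by 4.58 (log2), and by 5.79 without those that may match several transcripts. The transporter Slc47a1 was 6.07-fold lower, with a limma adjusted p of 0.0578 without diploid replicate 2 and 0.0664 without diploid replicate 3.

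X-linked genes were higher in the haploid lines as a group. The mean level of X-linked genes relative to autosomal genes was 0.388 ± 0.027 (log2, SD, n = 3) in the haploid lines and -0.388 ± 0.037 in the diploid lines, after centring each gene over the 6 arrays. The difference of 0.775 corresponds to 1.71-fold, and over all genes it was 0.465. The larger value rested on 297 X-linked and 8778 autosomal genes above the median level, and 93.9% of the X-linked genes were higher in the haploid lines. The exact two-sided permutation p was 0.1, the smallest that 3 lines against 3 allow. Set against autosomal genes by camera, the X-linked genes had p = 3.33e-35 with the preset correlation and p = 0.000511 with an estimated correlation.

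Of the X-linked genes, 251 passed the threshold as higher and 9 as lower in the haploid lines. Dusp9, a phosphatase of ERK, was 6.58-fold higher (log2 2.72 ± 0.17, limma adjusted p = 0.000876). AU015836 was 7.75-fold higher and Heph, a copper-dependent iron oxidase, at least 7.22-fold higher, although the limma adjusted p of Heph was 0.0505 without diploid replicate 3. Against this direction, the kinase Stk26 was 2.24-fold lower (limma adjusted p = 0.00647). The chromatin remodeller Smarca1 (-1.19), Pwwp3b (-0.97) and Reps2 (-0.90, log2) were also lower. Smarca1 did not pass without diploid replicate 2 or 3 or haploid replicate 2 or 3 (limma adjusted p = 0.0869 to 0.137), Pwwp3b not without diploid replicate 2 or 3 or any one of the haploid replicates (0.0509 to 0.129), and Reps2 not without diploid replicate 2 or 3 or haploid replicate 2 (0.0548 to 0.0922). With the X chromosome's shift subtracted the difference was 1.94 for Dusp9, 2.18 for AU015836, 2.08 for Heph, -1.94 for Stk26, -1.96 for Smarca1, -1.74 for Pwwp3b and -1.67 for Reps2 (log2). On the Y chromosome, Uba1y was at least 6.59-fold and Uty at least 2.65-fold lower. Uba1y did not pass without diploid replicate 2 or 3 or haploid replicate 2 or 3 (limma adjusted p = 0.0701 to 0.106), and Uty not without diploid replicate 2 or 3 or haploid replicate 2 (0.0646 to 0.0824). Uba1y stood at 5.53 in diploid replicate 1 and at 8.05 and 7.65 in the other diploid lines. It differed by -3.49 (log2) without diploid replicate 1 and by -1.94 with the mean of its probe sets. The Y-linked demethylase Kdm5d differed by -0.48 (log2, limma adjusted p = 0.214) and was dim in both groups, with means of 4.54 in the haploid and 5.02 in the diploid lines. The Y-linked list had 3 of 7 members lower over all genes and 3 adjusted over the list alone, and did not pass the set test (camera adjusted p = 0.0734, against 0.0199 without diploid replicate 1 and 0.0346 with the mean of a gene's probe sets).

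Of 34 X-linked housekeeping genes, 25 rose and none fell, and 28 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.37e-16, and adjusted p = 0.0187 with an estimated correlation). The translocon protein Ssr4 rose 2.98-fold, the nuclear membrane protein emerin, Emd, 2.69-fold, the chromatin remodeller Atrx 2.4-fold and the nucleotide synthesis enzyme Prps1 2.38-fold. The glycolytic enzyme Pgk1 rose 1.47-fold, but did not pass without diploid replicate 2 or 3 or haploid replicate 2 (limma adjusted p = 0.0641 to 0.0717). After subtraction of the X chromosome's shift Pgk1 differed by -0.22 and Atrx by 0.49 and did not pass, while Ssr4 (0.80), Emd (0.66) and Prps1 (0.48, log2) did. In the X-inactivation region 4 of 9 genes rose, with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0211, and adjusted p = 0.482 with an estimated correlation). They were Nap1l2, Ftx, Chic1 and Rlim, a ubiquitin ligase, between 1.49-fold and 2.49-fold. The set did not pass without diploid replicate 1 (camera adjusted p = 0.0806) or among genes above the median level (0.165), and Nap1l2 and Rlim did not pass without diploid replicate 2 or 3 or haploid replicate 2 or 3 (limma adjusted p = 0.0575 to 0.0631 and 0.0558 to 0.088). Rlim did not pass with the mean of its probe sets either (0.0836). With that shift subtracted none of these 4 passed, and Rlim turned to -0.20. Xist, the RNA that coats an inactive X, differed by 0.28 ± 0.26 (log2, SE, limma adjusted p = 0.499), turning to -0.50 with the shift subtracted, and Tsix, its antisense RNA, by -0.67 (limma adjusted p = 0.0524). Tsix passed with the shift subtracted, at -1.45 (limma adjusted p = 0.00543), without diploid replicate 1 (0.0126), with array weights (0.0143) and with trend and robust settings (0.0451).

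Genes on chromosomes 8 and 11 were lower in the haploid lines. The median shift of chromosome 8 against all autosomal genes was -0.35 (log2), over 505 genes of which 81% were lower, and that of chromosome 11 was -0.30, over 792 genes of which 76.6% were lower. By camera the adjusted p over 19 autosomes was 2.93e-16 for chromosome 8 and 1.91e-14 for chromosome 11. With an estimated correlation it was 0.00872 and 0.016. Over all genes, dim ones included, the median shifts were -0.165 and -0.134, and both passed. The shift of chromosome 8 was 0.16, 0.17 and 0.17 in the 3 diploid lines and -0.19, -0.18 and -0.17 in the haploid lines. These chromosomes held 13.1% of the tested genes and 491 (38.8%) of the 1266 genes that fell. No other autosome passed on all 6 arrays, while 4 autosomes passed without diploid replicate 3 and 3 without haploid replicate 3. Chromosome 6 stood at 0.29 in diploid replicate 1 and at -0.11 and -0.10 in diploid replicates 2 and 3.

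**Figure D1:**
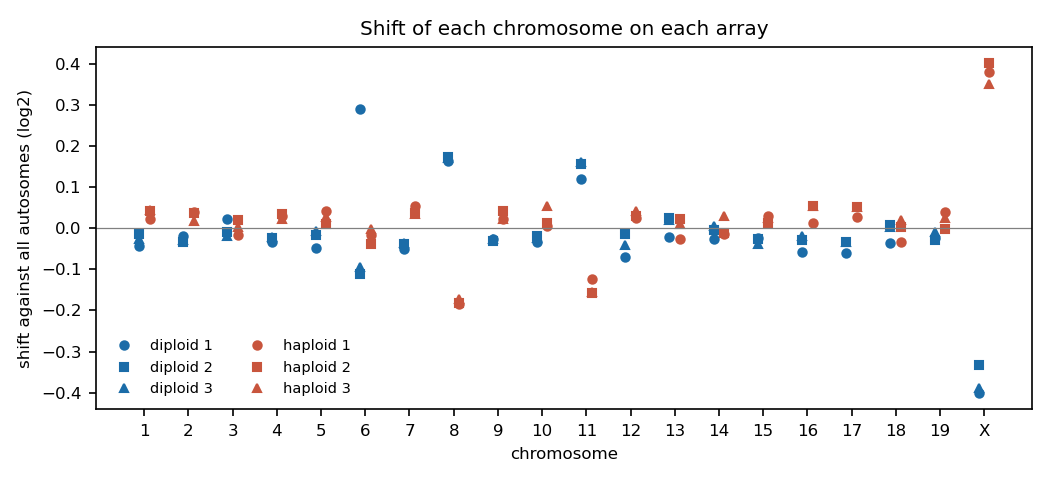
Median shift of each chromosome against all autosomal genes (log2, vertical axis) by chromosome (horizontal axis), with 1 point per array for 3 diploid and 3 haploid lines. Chromosomes 8 and 11 lie above 0 in all diploid and below 0 in all haploid lines, X lies the other way, and chromosome 6 stands at 0.29 in diploid replicate 1.

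Targets of the tumour suppressor p53 were higher in the haploid lines. Of 27 measured targets 12 rose and none fell, and 16 rose and none fell adjusted over the list alone (camera adjusted p = 1.73e-06, and adjusted p = 0.482 with an estimated correlation). Ddit4l, an inhibitor of mTOR signalling, rose 2.63-fold (log2 1.40 ± 0.12, SE, n = 3 per group, limma adjusted p = 0.00194). The apoptosis-linked membrane protein Perp rose 2.56-fold, the antiproliferative gene Btg2 2.46-fold and Dcxr 2.36-fold. Perp did not pass without any one of the diploid replicates or without haploid replicate 2 or 3 (limma adjusted p = 0.0538 to 0.102), Btg2 not without diploid replicate 2 (0.0503) or 3 (0.0549), and Dcxr not without diploid replicate 2 or 3 or haploid replicate 1 or 2 (0.0853 to 0.131). The cell cycle inhibitor Cdkn1a differed by 0.63 ± 0.22 (log2, limma adjusted p = 0.108), and by 0.80 with array weights, where it passed (0.0353).

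Genes of core and naive pluripotency moved in both directions. Of 31 measured genes 8 rose and 3 fell, and 11 rose and 4 fell adjusted over the list alone, and the list did not pass the set test (camera adjusted p = 0.0601). Its camera adjusted p was 0.0197 without diploid replicate 2, 0.0442 without diploid replicate 3 and 0.043 without haploid replicate 1. Dppa3, a maternal factor that protects DNA methylation in the zygote, rose 6.34-fold (log2 2.67 ± 0.45), the transcription factor Foxd3 2.43-fold and Klf4 1.6-fold. The central factors Nanog and Pou5f1 rose 1.39-fold and 1.32-fold. The nuclear receptor Nr5a2 fell 2.58-fold, or by 0.32 (log2) with the mean of its probe sets, and the RNA-binding protein Lin28a 2.82-fold. Sox2 (0.09), Esrrb (0.29) and Zfp42 (-0.25, log2) did not pass, with limma adjusted p of 0.68, 0.0985 and 0.203. Without diploid replicate 2 and without diploid replicate 3 the limma adjusted p was 0.0503 and 0.0572 for Dppa3, 0.0516 and 0.0552 for Foxd3, and 0.0648 and 0.0716 for Lin28a. Nanog did not pass without diploid replicate 2 or 3 or haploid replicate 2 or 3 (0.0522 to 0.0906), and Pou5f1 not without diploid replicate 2 or 3 or any one of the haploid replicates (0.0503 to 0.0874), nor with chromosome shifts subtracted (0.0653). Zfp42, on chromosome 8, turned to 0.08 with the chromosome's shift subtracted.

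Markers of later cell types showed no shared direction. Of 19 primed or formative epiblast genes 2 rose and 2 fell over all genes and adjusted over the list alone (camera adjusted p = 0.784), among them the DNA methyltransferase Dnmt3a, which fell 2.85-fold by the brightest of its probe sets and by 0.83 (log2) with their mean. Of 19 primitive streak and mesoderm genes 3 rose and 1 fell by either adjustment (camera adjusted p = 0.513), led by the transcription factors Gsc (3.52-fold) and Gata2 (2.46-fold). Of 21 endoderm genes 1 rose and 3 fell by either adjustment (camera adjusted p = 0.784), and the collagen Col4a1 fell 2.11-fold, with a limma adjusted p of 0.0564 without diploid replicate 2. Of 17 neural ectoderm genes 1 rose and 1 fell by either adjustment, the transcription factors Sox21 (1.46-fold) and Sox1 (2.5-fold), and the set had a camera adjusted p of 0.784. Sox21 passed on all arrays and without haploid replicate 2, but not without any other array (limma adjusted p = 0.0871 to 0.129), after quantile normalization (0.0692), with array medians aligned (0.0502) or with the mean of its probe sets (0.0522). Sox1 did not pass without diploid replicate 3 (0.0621) or haploid replicate 2 (0.0563), and differed by -0.80 (log2) with the mean of its probe sets. Of 17 trophoblast genes 2 rose and 3 fell by either adjustment (camera adjusted p = 0.879), and the signalling factor Bmp4 fell 5.02-fold and the keratin Krt8 4.62-fold.

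The kinases inhibited in 2i medium have known target genes. Of 19 feedback targets of the ERK pathway 3 fell and none rose over all genes and adjusted over the list alone (camera adjusted p = 0.153). The ERK pathway inhibitor Spred1 fell 2.45-fold (limma adjusted p = 0.00539). Junb on chromosome 8 and Spred2 on chromosome 11 differed by -0.83 and -0.68 (log2). With chromosome shifts subtracted they differed by -0.505 and -0.413 and did not pass (limma adjusted p = 0.15 and 0.134). Junb did not pass without diploid replicate 2 or 3 or haploid replicate 1 or 3 (limma adjusted p = 0.101 to 0.147). Spred2 did not without diploid replicate 2 or 3 or haploid replicate 1 or 2 (0.0836 to 0.127). The set passed without diploid replicate 1 (camera adjusted p = 0.0391) and without haploid replicate 3 (0.0208). Of 19 Wnt and beta-catenin targets 2 rose and 3 fell by either adjustment (camera adjusted p = 0.784), with the transcription factor Sox4 3.47-fold lower, or by 0.94 (log2) with the mean of its probe sets, and the homeobox gene Cdx1 1.83-fold higher.

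Cell cycle genes moved in both directions. Of 24 G1 cyclins and inhibitors 3 rose and 1 fell, and 4 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.134). The retinoblastoma gene Rb1 rose 3.18-fold and the cyclin Ccnd3 2.07-fold, and the kinase Cdk6 fell 5.2-fold, with a limma adjusted p of 0.0502 without diploid replicate 3. With the mean of their probe sets the log2 difference was 1.01 for Rb1, 0.37 for Ccnd3 and -1.68 for Cdk6, and all 3 passed. Of 33 DNA replication genes 1 rose and 4 fell, and 3 rose and 8 fell adjusted over the list alone (camera adjusted p = 0.0701). The helicase subunit Mcm5, the licensing factor Cdt1 and Gins3 fell 1.5-fold, 1.49-fold and 1.4-fold, and all 3 lie on chromosome 8. With that chromosome's shift subtracted they differed by -0.26, -0.25 and -0.16 (log2) and did not pass. Mcm5 did not pass without diploid replicate 3 (limma adjusted p = 0.055) or without the probe sets that may match several transcripts (0.0918), and Gins3 not without diploid replicate 2 or 3 or haploid replicate 2 (0.0569 to 0.0686). The replication list passed without haploid replicate 1 (camera adjusted p = 0.02), among genes above the median level (0.0181) and after quantile normalization (0.0167). Of 35 genes of G2/M and mitosis 6 rose and 3 fell, and 9 rose and 6 fell adjusted over the list alone (camera adjusted p = 0.784).

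Fibroblast markers, listed because ES cells are often grown on feeder fibroblasts, were lower in the haploid lines. Of 23 measured markers 5 fell and none rose, and 8 fell and none rose adjusted over the list alone (camera adjusted p = 0.0119, and adjusted p = 0.482 with an estimated correlation). Among genes above the median level the list did not pass (camera adjusted p = 0.12). The collagen Col1a2 fell 6.16-fold, the smooth muscle genes Tagln 4.65-fold and Acta2 4.11-fold, and the intermediate filament gene Vim 2.38-fold. Vim did not pass without any one of the diploid replicates or without haploid replicate 3 (limma adjusted p = 0.0507 to 0.0993). With the mean of their probe sets Col1a2 differed by -1.89 and Acta2 by -0.93, and Acta2 differed by -0.46 (log2, limma adjusted p = 0.0991) without the probe sets that may match several transcripts. The collagen Col3a1 stood at 8 in diploid replicate 1, at 5.17 and 4.9 in the other diploid lines and at 3.84 to 4.24 in the haploid lines (log2). The beta-actin 3' minus 5' difference given above, a control of RNA quality and not a fibroblast marker, was also higher in the diploid lines.

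Genes of major histocompatibility complex class I and the interferon response included 2 of 20 that fell and 1 that rose, and 5 that fell and 1 that rose adjusted over the list alone (camera adjusted p = 0.03, and adjusted p = 0.482 with an estimated correlation). The interferon-induced gene Ifit2 fell at least 2.53-fold and the transcription factor Irf1 1.73-fold, while the membrane protein Ifitm3 rose 2.32-fold. Ifitm3 did not pass without diploid replicate 2 or 3 or any one of the haploid replicates (limma adjusted p = 0.0655 to 0.145), with chromosome shifts subtracted (0.0536) or with chromosomes 6, 8, 11, X and Y left out (0.0514). The list did not pass without haploid replicate 3 (camera adjusted p = 0.0625), among genes above the median level (0.175) or with those chromosomes left out (0.0549).

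Genes listed for a 2-cell-like state, that of the 2-cell embryo and of a rare fraction of ES cells, included 2 of 10 that rose and none that fell, over all genes and adjusted over the list alone (camera adjusted p = 0.0189, and adjusted p = 0.482 with an estimated correlation). The mean difference of the list was 1.29 (log2), and 0.81 without haploid replicate 3, where it still passed (camera adjusted p = 0.00387). In haploid replicates 1 and 2 Zfp352, Tcstv3, Tdpoz1, Eif1a and Sp110 differed from the diploid lines by -0.02 to 0.11. Eif1a stood at 11.6 to 11.66 on every array, so not every member marks such a state. The call of the list does not by itself show a 2-cell-like state in all haploid lines. Pramel7 rose 5.47-fold and Pramel6 4.72-fold, or by 1.45 and 1.27 (log2) with the mean of their probe sets. Without the probe sets that may match several transcripts, Pramel6 differed by 0.30 (log2, limma adjusted p = 0.187) and Pramel7 by 0.44 (limma adjusted p = 0.0348).

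**Figure D2:**
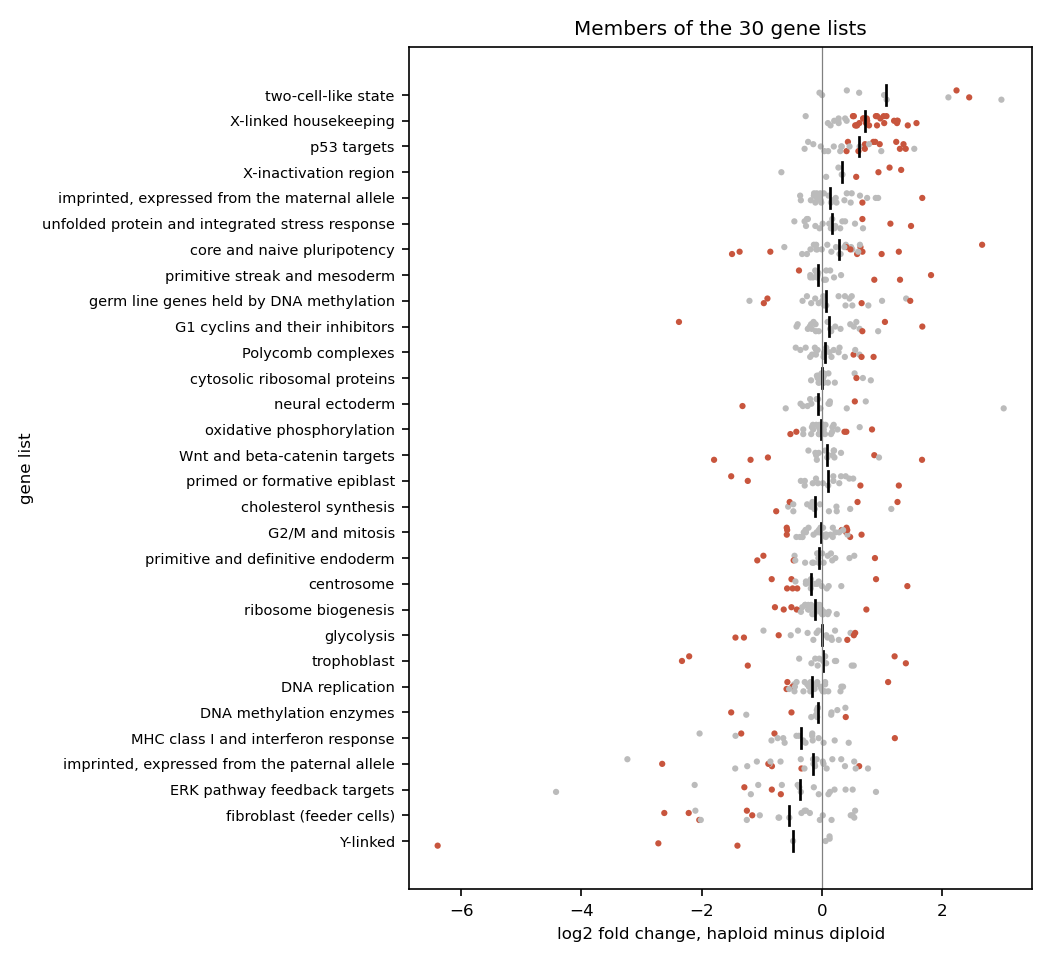
Log2 fold change, haploid minus diploid (horizontal axis), of each measured member of the 30 gene lists (vertical axis), with red points for genes past an adjusted p of 0.05, grey points for the others and a black bar at the list's median. The median of the X-linked housekeeping list was 0.71, that of the p53 targets 0.61 and that of the fibroblast list -0.54.

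Genes listed as imprinted, that is expressed from 1 parental allele in at least some tissues, were examined as 2 lists. The arrays do not tell alleles apart, so whether these genes were imprinted in these lines was not tested. Of 28 paternally expressed genes 1 rose and 4 fell, and 1 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.114, and 0.00497 without haploid replicate 3). The phosphatase gene Inpp5f fell 6.31-fold (log2 difference -2.66 ± 0.11, SE, limma adjusted p = 0.000362), Nnat 1.85-fold and the adaptor gene Gab1 1.78-fold. Nnat was dim, with means of 5.05 in the haploid and 5.94 in the diploid lines. Gab1 lies on chromosome 8, whose median shift was -0.35 (log2), and still passed with that shift subtracted. Peg3, a zinc finger gene, stood at 8.78 ± 2.33 (log2, SD, n = 3) in the haploid and 9.63 ± 0.24 in the diploid lines (limma adjusted p = 0.605), and without haploid replicate 3 it differed by -2.19 (log2, limma adjusted p = 0.00647). Igf2, a growth factor, and Snrpn differed by -1.08 and -0.29 (log2), with limma adjusted p of 0.183 and 0.324, and Igf2 passed without diploid replicate 1 (-1.70, limma adjusted p = 0.00794) and with array weights (-1.47, 0.0363). Of 28 maternally expressed genes 2 rose and none fell by either adjustment (camera adjusted p = 0.163), and these were Qpct (3.18-fold) and the tetraspanin Cd81 (1.6-fold). Meg3 and the growth factor receptor Igf2r differed by 0.24 and 0.03 (log2), with limma adjusted p of 0.584 and 0.914, and both changed sign under some alternatives.

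Arrays resembled each other more within groups than between them. Pearson's r across genes, which are not independent replicates, averaged 0.9904 ± 0.0035 (SD, 6 pairs) within groups and 0.9766 ± 0.0034 (SD, 9 pairs) between groups. The difference of 0.0138 was reached by 1 of the 10 splits of the 6 arrays, the real one, and the highest other split gave 8.8e-05. A share of 0.1 is the smallest this design allows.

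The last comparison set haploid replicate 3, the transgenic line, against haploid replicates 1 and 2. With limma 68 genes passed, 44 higher and 24 lower in haploid replicate 3, and the single line was assumed to vary like the others. The genes named here were chosen after their values were seen. Of the 10 genes of the 2-cell-like list 4 passed, all higher in that line: Tcstv1 by 13.6-fold, Tcstv3 by at least 7.86-fold, Usp17la by 8.71-fold and Zfp352 by 3.7-fold, with limma adjusted p of 0.00108, 0.0107, 0.00557 and 0.00822. Of the others, Arg2, Pramel7 and Tdpoz1 differed by 1.10 to 1.48, Eif1a by 0.06, Sp110 by -0.44 and Pramel6 by -0.96 (log2). Of 28 paternally expressed imprinted genes 3 passed, and Peg3, Mest and Impact were 15.8-fold, 10.7-fold and 4.43-fold higher there. Mest, a hydrolase-like gene, stood at 10.15 (log2) in haploid replicate 3, 6.88 and 6.58 in haploid replicates 1 and 2, and 10.85 to 11.46 in the diploid lines. In the same order, Impact stood at 11.59, at 9.74 and 9.14, and at 11.41 to 11.74. Mest and Impact were thus low in haploid replicates 1 and 2 rather than raised above the diploid lines in haploid replicate 3. Peg3 stood at 11.43, at 7.8 and 7.1, and at 9.36 to 9.78, so it also exceeded the diploid lines. The homeobox genes Crxos and Otx2 were at least 41.1-fold and 8.33-fold lower in haploid replicate 3, and H2-K1, which encodes a class I histocompatibility antigen, 4.16-fold lower. The count was 26 among genes above the median level, 25 without diploid replicate 3, 33 without diploid replicate 2 and 123 without haploid replicate 2. Strain, passage and transgene differed together between these lines.

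**Figure D3:**
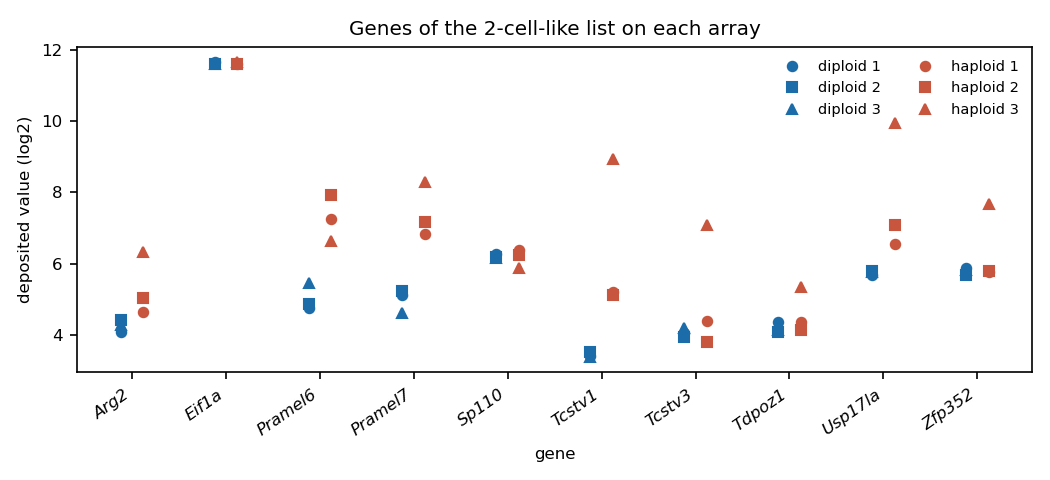
Deposited log2 value (vertical axis) of each measured gene of the 2-cell-like list (horizontal axis), with 1 point per array for 3 diploid and 3 haploid lines. Haploid replicate 3 is the highest array for Tcstv1 (8.92), Tcstv3 (7.07), Usp17la (9.93) and Zfp352 (7.67).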

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

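The tests of other splits of the arrays, of feeder cells, and of both explanations for the 2-cell-like genes were written after part of the result had been seen; the others were written before. Signal outside the named genes appeared in 386 of 10092 probe sets with no single gene name, which passed the same threshold in limma, 234 higher and 152 lower in the haploid lines. With 3 arrays against 3 the 10 possible splits cannot give a share under 0.05. For genes, 1 of the 10 splits reached the real count of 2707, and the highest other split gave 0. For gene lists, 9 of the 10 splits reached the real count of 6, and the highest other split gave 9. For autosomes, 10 of the 10 splits reached the real count of 2, and the highest other split gave 3. Every other split puts haploid and diploid arrays on both sides. That keeps part of the real difference between the sides and widens the spread within them, so these counts cannot tell whether the calls arose by chance.

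Genes of chromosomes 8 and 11 were lower in the haploid lines. Normalization that depends on expression level is argued against, since the lowest median of 1000 sets of other autosomal genes matched on level was -0.014, above the shifts of -0.35 and -0.30. Extra copies of these chromosomes in some cells of the diploid lines remain a candidate explanation. Each chromosome was lower in all 4 of its blocks in gene order, with a highest median of -0.217. The blocks show a shift along the whole chromosome, which other causes that act along it would give too. They do not single out extra copies. By contrast, 3 copies for 2 in every cell would give 0.585 on an uncompressed scale. Strain differences within the probes cannot be told apart from extra copies by the test set beforehand. The share of lower genes was 76.6% on chromosome 11. Its exact binomial interval (73.5% to 79.5%) spans the limit of 75%, and strain differed with ploidy. On chromosome 8 the share was 81% and its interval (77.3% to 84.3%) lay above that limit, but the test asked this of both chromosomes. Biological effects of ploidy on these chromosomes were not tested.

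Fibroblast markers were lower in the haploid lines, and feeder cells left in the diploid cultures may be a source. Of 8 abundant matrix transcripts 6 were lower by at least 0.5 (log2). Among these 6 only Col1a2 passed (limma adjusted p = 0.00326), and the others had a limma adjusted p of 0.0571 to 0.156. Fn1 and Sparc differed by 0.16 and 0.54, so the test did not reach either limit set for it. Lower activity of actin and SRF target genes, the other explanation tested, also stayed between its limits, with a median of -0.23 over 20 genes outside the marker list (camera p = 0.175 with an estimated correlation), of which 6 passed as lower (Cnn1, Cnn2, Myl9, Tpm4, Tgfb1i1 and Tpm2) and 0 as higher. A shorter list of 12 such genes, noted earlier but run second, gave -0.22 (camera p = 0.326 with an estimated correlation). The source of the markers cannot be told apart here, and the 3 diploid lines differed among themselves, with Lox at 9.86 in diploid replicate 1 and at 6.13 and 5.29 in the others.

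The 2-cell-like genes were higher in haploid replicate 3 than in haploid replicates 1 and 2, by a median of 1.39 (log2) over 10 genes, of which 7 were at least 1 higher while Sp110 and Pramel6 were lower by 0.44 and 0.96. Cross-hybridisation within the Tcstv gene family would not by itself give the whole pattern, since 5 members outside that family were also at least 1 higher. Whether the probe sets of Tcstv1 and Tcstv3, or of other multicopy members, read more than 1 gene was not tested. A wider scatter of unrelated dim genes on this array is argued against, since none of 10000 sets matched on level reached this median. The highest was 0.32 (permutation p = 1e-04 with the real set counted). This p measures the draw of genes on 1 array and not the spread between lines. It treats the genes as independent, which members of a gene family may not be. The test was also written after part of the result had been seen. A larger share of cells in that state is a biological hypothesis, which may equally reflect strain, passage or the transgene of this 1 line, and none of these was tested.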

How the results depend on the processing

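Chromosome shifts subtracted, chromosomes left out, arrays left out of the similarity and line results, and the estimated correlation for autosomes were chosen after the data were examined. No paired analysis was possible because replicate numbers only name lines and no line belongs to both groups. The gene count was 4687 with every probe set on its own, 654 with at least 2-fold and 1639 with chromosomes 6, 8, 11, X and Y left out, by the construction of these alternatives. It was 970 to 2428 without 1 array, lowest without diploid replicate 3, then 1196 without diploid replicate 2 and 1429 without haploid replicate 2, and stayed within 1.5 times of 2707 under the others. The X-linked difference ran from 0.755 to 0.799 without 1 array and was 0.465 over all genes, and it stayed past its camera threshold under every alternative run. The autosome count was 2 to 4 without 1 array, 4 without diploid replicate 3, and the shifts of chromosomes 8 (-0.359 to -0.327) and 11 (-0.307 to -0.287) passed each time, as they did over all genes (-0.165 and -0.134). The list count was 1 with an estimated correlation, 3 with those chromosomes left out, 4 with chromosome shifts subtracted, 4 above the median level, 8 with the mean of probe sets, 9 after quantile normalization and 6 to 9 without 1 array. The similarity difference was 0.0485 above the median level and 0.0122 to 0.0171 without 1 array. The line count was 26 above the median level and 25 to 123 without 1 array (25 and 33 without diploid replicates 3 and 2, 123 without haploid replicate 2). Except where fewer genes or arrays explain it, the cause was not tested.

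Of 2442 values of named genes under the alternatives, 2054 kept direction and side of the threshold, 369 no longer passed, 8 newly passed and 11 reversed; 53 of the 131 named genes that passed did so under every alternative run on them except the 2-fold threshold, while alternatives that drop genes were not run on the genes they drop. Reversals with chromosome shifts subtracted were Rlim -0.202, Dkc1 -0.033, Pgk1 -0.22, Zfp42 0.079, Xist -0.498 and Igf2r -0.075, and the X-inactivation list at -0.30 and the X-linked housekeeping list at -0.06, by construction for X. Igf2r was also -0.006 after quantile normalization, -0.09 with array weights, -0.151 without diploid replicate 1, -0.033 without haploid replicate 3 and 0.135 without diploid replicate 2, and Meg3 -0.037 without diploid replicate 1 and 0.519 without diploid replicate 2. Of 354 list values 324 kept their side, 11 no longer passed, 17 newly passed and 2 reversed. Signal over background limits dim genes such as Pramel6, Pramel7 and Prss23, which lay below 6.83 in the diploid lines, the median level of the probe sets with 1 gene symbol.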

Other observations

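The tests of the hypothesis on the X chromosome were written before their results were seen, while the chromosome 6 values and the subtraction of chromosome shifts were chosen after. Of 31 ribosome biogenesis genes 1 rose and 4 fell by either adjustment (camera adjusted p = 0.0734, against 0.0391 without diploid replicate 1, 0.0419 among genes above the median level and 0.0173 after quantile normalization). Utp4 on chromosome 8 fell 1.72-fold (limma adjusted p = 0.0558 without diploid replicate 3 and 0.0651 with the chromosome's shift subtracted) and Pes1 on chromosome 11 fell 1.55-fold, while the X-linked Dkc1, a pseudouridine synthase, rose 1.67-fold, or -0.03 (log2) with the X chromosome's shift subtracted. Of 20 glycolysis genes 3 rose and 3 fell, and 3 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.879). Pdk1, which inhibits pyruvate dehydrogenase, fell 2.71-fold and the enolase Eno3 2.46-fold. Of 33 oxidative phosphorylation genes 3 rose and 2 fell by either adjustment (camera adjusted p = 0.784), with the X-linked complex I gene Ndufa1 1.78-fold higher, or 0.06 (log2, limma adjusted p = 0.676) with the X chromosome's shift subtracted. Of 19 cholesterol synthesis genes 2 rose and 2 fell, and 4 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.926). Of 21 genes of the unfolded protein and integrated stress response 3 rose and none fell by either adjustment (camera adjusted p = 0.116), led by the transcription factor Cebpb (2.79-fold). Of 26 ribosomal protein genes 1 rose, Rps27 (1.49-fold, which did not pass under most alternatives, with a limma adjusted p of up to 0.15 without 1 array), and 0 adjusted over the list alone (camera adjusted p = 0.513).

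Among chromatin and centrosome genes, 3 of 26 Polycomb genes rose and none fell by either adjustment (camera adjusted p = 0.159, against 0.0174 with the mean of a gene's probe sets), among them Yaf2, a Ring1-binding protein, by 1.58-fold. Of 14 DNA methylation enzymes 1 rose and 2 fell, and 2 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.771). Of 22 centrosome genes 2 rose and 5 fell by either adjustment (camera adjusted p = 0.116, against 0.0391 without diploid replicate 1 and 0.0368 after quantile normalization). Of 23 genes of a germ line list, in which Zfp42 and Syce1 were expressed in all lines, 2 rose and 2 fell, and 2 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.457). Taf7l, an X-linked gene of spermatogenesis, rose 2.77-fold, or 0.70 (log2) with the shift subtracted, and Tdrkh fell 1.95-fold.

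A hypothesis on the X chromosome is that haploid cells hold 1 X per set of autosomes where male diploid cells hold 1 X per pair of sets, which would raise X-linked genes all along the chromosome by up to 1 (log2). The lowest median shift among 4 blocks of X in gene order was 0.657 and the highest 0.817, as this hypothesis predicts. Any other change spread along the whole of X would give this too, so the blocks do not single out the hypothesis. A minority of strongly changed X-linked genes is argued against, since 93.9% of these genes were higher (90.6% to 96.4%, exact binomial). The interval treats these genes as independent and does not measure the spread between lines. Strain differed between the groups too and was not tested.

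In diploid replicate 1 the genes of chromosome 6 were higher than in diploid replicates 2 and 3 by a median of 0.379 (log2), with 90.8% of the genes higher and medians between 0.358 and 0.388 in 4 blocks in gene order.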
